A study of Mus musculus with 30 samples.

How the data were processed

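Labelled RNA from liver and muscle of the same 15 mice had been hybridized to Illumina MouseRef-8 bead arrays, 1 array per mouse and tissue, and the files used here hold 1 table of 15 arrays for each tissue. Per the file headers, the deposited intensity of each probe is the mean bead signal exported by GenomeStudio 1.6.0, without background subtraction or normalization. The deposited detection p-value of each probe and array, per the file headers, compares the probe with negative control beads and is not adjusted. The authors also deposited a z-score for each probe and array, a score made by centring and dividing the natural log signals of an array, and this score was used here only as an alternative. The authors' description says that undetected spots were filtered out before the z-scores were made, but the values match z-scores over all probes of an array, and 4450 liver and 9107 muscle probes with z-scores hold at least 1 undetected value. Probe names were taken from the probe identifier columns, because the first column of the muscle table is shifted by 1 line (18041 of its names differ from the gene name on the same line, and 98 from the one next to it). Each table holds 25594 probes. Symbols were updated from the mouse gene table by Entrez number for 23586 probes and by RefSeq accession for 733, and 31 symbols that a spreadsheet had turned into dates were repaired in this way. The chromosome of a probe is the one in the file. The build of the probe coordinates is not given in the sources used here, and 8.45% of 21791 coordinates fell inside their gene in GRCm38.p6, so positions are not printed.

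The following choices were made before the data were examined unless said otherwise. Intensities were background-corrected from the detection p-values, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (R 4.3.3, offset 16), each tissue on its own. Probes with a detection p under 0.02 on at least 5 of the 15 arrays were tested, 11148 in liver and 10983 in muscle. The 3 diets were compared in a linear model over the 15 arrays of a tissue with lmFit and eBayes with an intensity trend, which pools the spread across probes and groups. P-values are two-sided and were adjusted by Benjamini-Hochberg over the probes of a comparison with a threshold of 0.05. The tissue difference, liver change minus muscle change, came from a joint model of all 30 arrays on the 9164 probes past the filter in both tissues. Nothing pairs the mice of different diets. The labels give both tissues of a mouse the same number. By the design set beforehand, the mouse entered as a block only in an alternative. Same-mouse deviations from the group means correlated between the tissues with a median of 0.0671 (-0.0652 to 0.362), against -0.0104 for other mice of the diet. Deviations cancel within a group, which ties the second value to the first, so it is no independent reference. For arrays, the number of arrays limits the precision, and errors are SD over 5 arrays or the SE of a log2 fold change.

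Genes were also tested in 36 lists, 26 of pathways and 10 of cell type markers, of which 28 had at least 5 measured genes in each tissue and 23 in both. Each gene stood for its brightest tested probe. camera compared the genes of a list with all others with a correlation preset at 0.01, and again with the correlation estimated from the data, where 0 calls held within either tissue and 2 held for the tissue difference of metformin. fry tested whether the genes of a list move, on balance, one way, which does not compare them with other genes. Members past the test were counted over all probes and adjusted over the list alone.

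Genes are named by a rule. For each comparison with the standard diet, these are the 6 highest and 6 lowest log2 fold changes past the test that keep their direction with each array left out, without clones and gene models. Added to them are the 3 members with the smallest p of each list that passed or held a called gene, the 6 genes with the smallest p where fewer than 6 probes passed, and a few metabolic genes fixed beforehand. For the other comparisons, the rule takes the 4 highest and 4 lowest. A few genes that the rule takes are not reported here, though the lists and probe counts include them. Several probes of a gene that differ are stated. Where a group has no detected array, a fold is given only as a bound against the detection level.

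The correlation of the metformin and restriction fold changes used 1 probe per gene, with 100 simulations of unchanged groups that share their standard diet arrays and with the mean of the 20 ways to give 2 of those arrays to one contrast and 3 to the other. The steps were tested on simulated data in which 200 genes were changed in each comparison. At a log2 change of 1, the model found 88 to 90 of 100 changed genes in liver and 46 to 57 of 100 in muscle, and at 2 it found 100 and 91 to 94. For the tissue differences it found 42 and 44 of 100 at 1, and 91 and 90 at 2. Across all comparisons these fits gave 0.746 to 6 percent false calls. camera found the shifted list in both tissues and called 0 others, but the simulated genes were drawn independently of each other. This run therefore says nothing about false list calls among correlated genes.

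The alternatives were z-scores rebuilt from the signals, the deposited z-scores, no background correction, median scaling in place of quantile normalization, no detection filter, a filter for detection on all 15 arrays, no intensity trend, robust variance, array weights, a fit of the compared groups alone, the mouse as a fixed or random block, the mean of all probes of a gene in the lists, and each array left out in turn. After seeing the data, a pair of alternatives was added: the log2 summed signal as a covariate in liver, and muscle normalized and fitted without the array of mouse 27. Splits of the arrays into other groups of 5 were counted over 100 of the 126 possible ones. No pair of arrays was identical, and all per-sample columns of the tables were used. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).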

Results

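Transcript levels were measured on Illumina MouseRef-8 bead arrays in liver and muscle of 15 male mice that entered their diet groups at 1 year of age. The groups were 5 mice on a freely eaten standard diet, 5 mice on that diet with 0.1% w/w metformin, a biguanide drug used against diabetes, and 5 mice on a 40% calorie restriction. Each mouse gave 1 liver array and 1 muscle array, 30 arrays in all, and each diet comparison rests on 5 arrays per group. The mean signal over all probes of a liver array was 981 ± 75.4 (SD, n = 5) on the standard diet, 736 ± 61.8 (SD, n = 5) under metformin and 769.1 ± 34.4 (SD, n = 5) under restriction. No metformin or restricted liver array was as bright as the dimmest standard diet array. Their highest means were 818.6 and 825, and the lowest standard diet mean was 901.6. A liver array detected 10580 ± 339 probes (SD, n = 5) on the standard diet, 10890 ± 234 (SD, n = 5) under metformin and 10580 ± 121 (SD, n = 5) under restriction. In muscle the mean signal was 525.9 ± 139 (SD, n = 5), 490.3 ± 37.7 (SD, n = 5) and 405.3 ± 65.5 (SD, n = 5) in the same order. The standard diet muscle arrays stood apart in their median signal, 142 to 152.4, against 129.9 to 138.9 under metformin and 123.3 to 134.5 under restriction. Their lowest signal, 90.2 to 91.9, was also above that of all other muscle arrays, 74.7 to 85.9, and no brightness covariate was fitted in muscle. A muscle array detected 10350 ± 435 (SD, n = 5), 10730 ± 389 (SD, n = 5) and 9722 ± 1620 probes (SD, n = 5). The muscle array of restricted mouse 27 detected 6848 probes, and its median correlation with the other muscle arrays was 0.712.

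**Figure D1:**
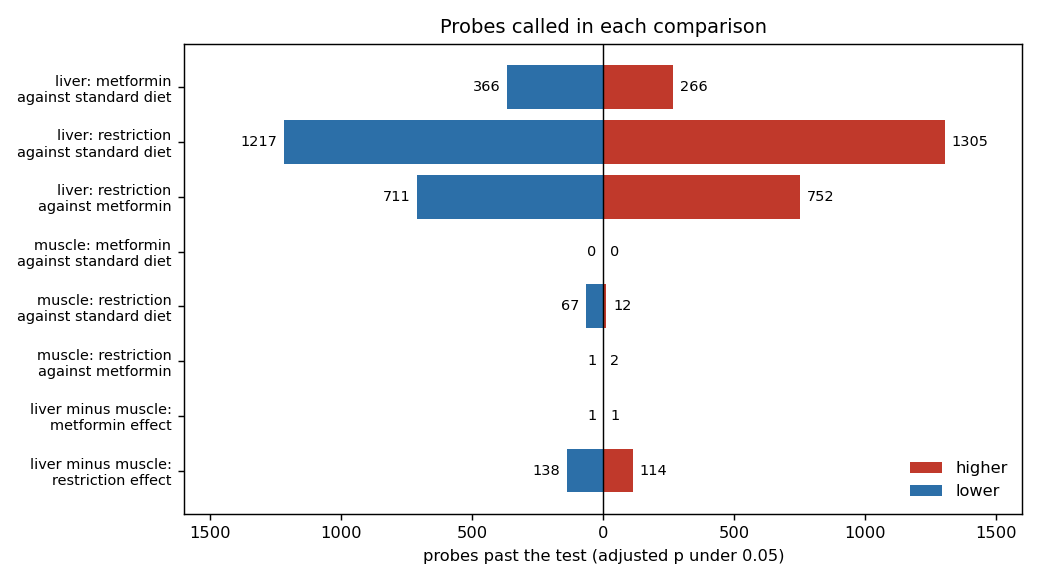
Number of probes past the test (adjusted p under 0.05) in each comparison, on the horizontal axis, with probes higher in the first group to the right and lower ones to the left. The bars hold 632 probes for metformin in liver, 2522 for restriction in liver and 0 for metformin in muscle, each from 5 arrays per group.

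Metformin against the standard diet in liver asks which hepatic transcripts the low dose of the drug changes. Dbp, an output transcription factor of the circadian clock (probe ILMN_2616226, chromosome 7), fell to a normalized log2 intensity of 7.82 ± 0.91 (SD, n = 5) from 11.63 ± 0.85 (SD, n = 5). The log2 fold change was -3.81 ± 0.39 (SE, limma adjusted p = 0.000174), with 5 of 5 metformin arrays below all standard diet arrays. Arntl, the clock activator that opposes it in phase (probe ILMN_2707510, chromosome 7), rose by 1.40 ± 0.17 on the log2 scale (adjusted p = 0.000749), again with 5 of 5 arrays apart. Lcn2, an iron-binding protein of the acute phase (probe ILMN_2712075, chromosome 2), fell to 8.72 ± 1.08 (SD, n = 5) from 12.32 ± 1.78 (SD, n = 5). This log2 fold change of -3.60 ± 0.68 (SE, limma adjusted p = 0.00776) came with 4 of 5 arrays below all standard diet arrays. Upp2, a uridine phosphorylase, fell by 2.05 ± 0.28 (adjusted p = 0.0012) on 4 of 4 probes. Fos, an immediate early transcription factor (probe ILMN_2750515, chromosome 12), rose from 9.79 ± 2.07 (SD, n = 5) to 12.48 ± 0.45 (SD, n = 5), a log2 fold change of 2.70 ± 0.68 (SE, limma adjusted p = 0.0326) with 5 of 5 arrays above all standard diet arrays. The call of Fos ended without standard diet mouse 2 or 3 or metformin mouse 21, 22 or 23, with a highest adjusted p = 0.0729.

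In all, 632 of the 11148 probes tested passed, 266 higher and 366 lower under metformin, from 569 of 8378 genes. Of these, 91 changed more than 2-fold, 40 upward and 51 downward, and 2730 probes had an unadjusted p under 0.05. Besides Fos, the strongest rises were those of Chrna4, a nicotinic receptor subunit (2.36 ± 0.62, adjusted p = 0.037), the immediate early genes Egr1 (2.06 ± 0.53) and Egr2 (1.98 ± 0.56), and Socs2, a growth hormone feedback inhibitor (1.70 ± 0.48). Ccn1, a matrix-associated growth regulator, had a second probe past the test, while its brighter probe was not (1.95, adjusted p = 0.052). Among the strongest falls, beside Dbp, Lcn2 and Upp2, were the serum amyloids Saa1 (-3.23 ± 0.71, adjusted p = 0.019) and Saa2 (-2.90 ± 0.68, adjusted p = 0.0236), near-identical copies whose probes may share signal, and Ciart, a clock repressor (-1.80 ± 0.48, adjusted p = 0.0403). The calls of Chrna4, Egr1, Saa1 and Saa2 ended without some single arrays (highest adjusted p 0.0837, 0.0721, 0.0514 and 0.0651). Those of Egr2, Socs2 and Ciart ended in 12, 13 and 13 of the 15 fits with 1 array left out (highest adjusted p 0.107, 0.12 and 0.107). Of the 47 named genes past the test here, 14 stayed past it with each array left out in turn and 2 in every other setting tried.

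The cholesterol synthesis list had a mean log2 fold change of 0.664 over 21 genes. Its isoprenoid enzyme Idi1 rose by 1.47 ± 0.36 (adjusted p = 0.0277), and Acat2, which makes acetoacetyl-CoA, rose by 0.87. Over all probes 6 of its genes rose and 0 fell, and 14 rose and 0 fell when adjusted over the list alone. camera gave the list an adjusted p = 2.6e-07, against adjusted p = 0.675 with an estimated correlation. fry, a rotation test of each list on its own, did not call this list (adjusted p = 0.111) or the acute phase list below (adjusted p = 0.155), and called the other 3 given here. The circadian clock list fell by a mean of 0.879 over 15 genes on the log2 scale. Of these, 1 gene rose and 8 fell over all probes, and 2 rose and 8 fell adjusted over the list alone (camera adjusted p = 8.11e-05, adjusted p = 0.145 with an estimated correlation). The acute phase list had a mean of -0.794 and a median of -0.258 over 22 genes. It held 0 up and 5 down over all probes and 0 up and 6 down adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.676 with an estimated correlation). Standard diet mouse 1 lay apart from the other 4 of its group here, with Lcn2 at 9.33 (others 12.54 to 14.04), Saa1 at 6.68 (10.22 to 11.82) and Saa2 at 6.36 (9.51 to 11.12). The acute phase call ended without standard diet mouse 2 (adjusted p = 0.066) and in 3 of 11 other settings (highest adjusted p 0.893). Ribosomal protein transcripts shifted up slightly, by 0.16 over 38 genes, with Rpl24 and Rps3 both 0.39 higher. There were 4 up and 0 down over all probes and 7 up and 0 down adjusted over the list alone (camera adjusted p = 1.91e-06, adjusted p = 0.339 with an estimated correlation). The list of ubiquitin ligases, autophagy genes and FOXO targets shifted by -0.196 over 17 genes, led by Fbxo31 (-0.79) and the autophagy kinase Ulk1 (-0.44). This list held 0 up and 2 down over all probes and 0 up and 5 down adjusted over the list alone (camera adjusted p = 0.0271, adjusted p = 0.145 with an estimated correlation), and its call ended in 1 fit with an array left out (adjusted p = 0.0975).

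Outside these lists, the stress kinase homolog Trib3 (-1.31, adjusted p = 0.00398), the coactivator Ppargc1b (-1.11, adjusted p = 0.00773) and the steroid and coumarin hydroxylase Cyp2a5 (-0.68, adjusted p = 0.0103), which has near-identical copies, fell. Atf4, a translation-controlled stress factor (0.98, adjusted p = 0.00645), and Ppp1r3b, a glycogen-targeting phosphatase subunit (0.90, adjusted p = 0.0101), rose. Of the genes fixed in advance, the gluconeogenic Pck1 (-0.53, adjusted p = 0.41) and G6pc (0.14, adjusted p = 0.77), Fasn, which makes fatty acids (0.88, adjusted p = 0.0796), and the hepatokine Fgf21 (1.30, adjusted p = 0.0925) did not pass. Igf1 (0.24, adjusted p = 0.0985, with a second probe at -0.15), its binding protein Igfbp1 (1.10, adjusted p = 0.553) and the bile acid enzyme Cyp7a1 (-0.27, adjusted p = 0.732) did not pass either. Cpt1a is not analysed here because it did not meet the detection filter. The probe count was 1163 without standard diet mouse 1 and 351, 183 and 315 without standard diet mice 2, 3 and 4, and 377, 264 and 309 without metformin mice 21, 22 and 23. It was 110 with the compared groups alone, 355 with no filter on dim probes and 421 with array weights. With the summed signal as a covariate it was 104, and the calls of Dbp (-3.49, adjusted p = 0.0552), Arntl (1.31, adjusted p = 0.0889), Fos (2.00, adjusted p = 0.536), Idi1 (0.56, adjusted p = 0.76), the cholesterol list (adjusted p = 0.21) and the ribosomal list (adjusted p = 0.0649) ended. Cyp2a5 lost its fold change as well as its call (-0.03, adjusted p = 0.965), and Egr1 (0.82), Ulk1 (-0.28) and Rpl24 (0.17) shrank and were not called.

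**Figure D2:**
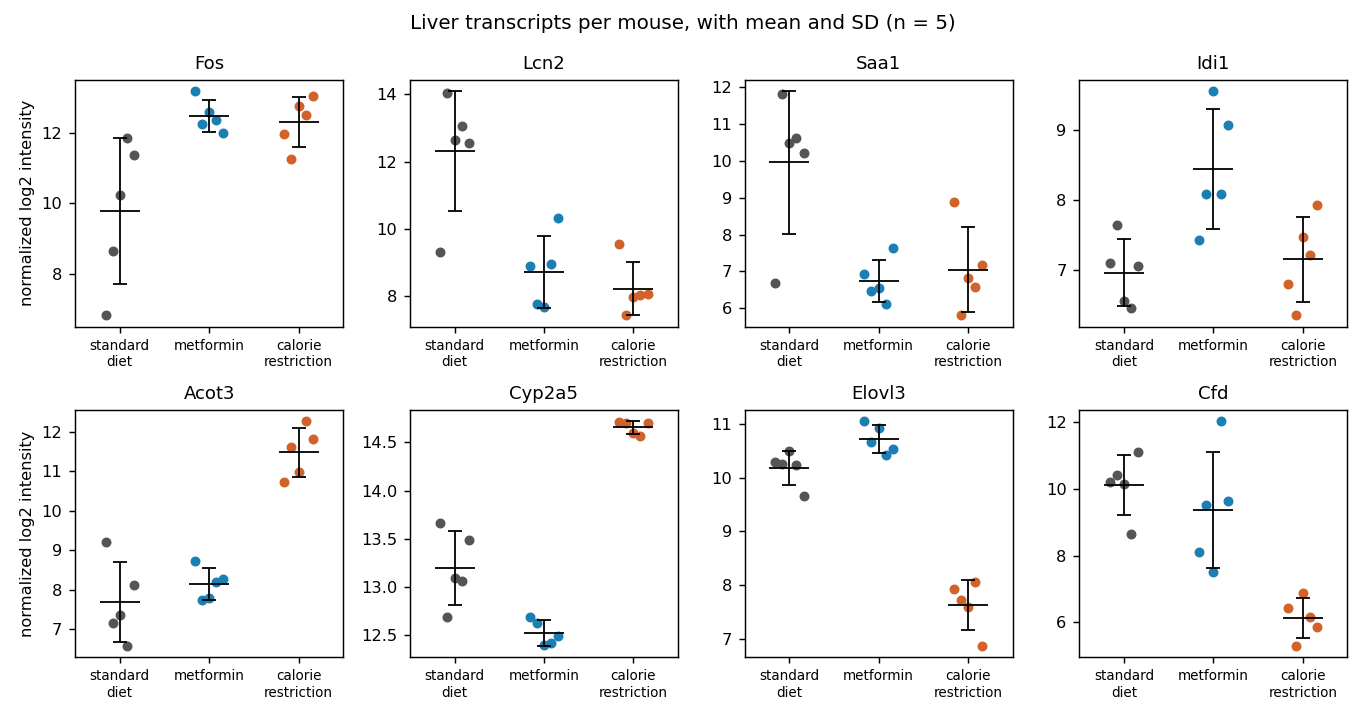
Normalized log2 intensity of 8 transcripts in liver (vertical axes) on the standard diet, under metformin and under calorie restriction, 1 point per mouse, with the mean and SD of 5 mice. Lcn2 is 8.72 under metformin and 8.23 under restriction against 12.32 on the standard diet, and Acot3 is 11.48 under restriction only, against 7.70.

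Calorie restriction against the standard diet in liver asks the same of reduced food intake, the reference intervention for long life in mice. Acot3, a peroxisomal acyl-CoA thioesterase that female livers express more (probe ILMN_2644827, chromosome 12), rose from 7.70 ± 1.01 (SD, n = 5) to 11.48 ± 0.62 (SD, n = 5), a log2 fold change of 3.78 ± 0.39 (SE, limma adjusted p = 6.09e-06). Elovl3, a fatty acid elongase that male livers express more (probe ILMN_2682207, chromosome 19), fell to 7.64 ± 0.46 (SD, n = 5) from 10.18 ± 0.32 (SD, n = 5), a log2 fold change of -2.54 ± 0.20 (SE, limma adjusted p = 6.28e-07). Cyp2a5 (probe ILMN_3159131, chromosome 7) went from 13.20 ± 0.38 (SD, n = 5) to 14.66 ± 0.07 (SD, n = 5), a rise of 1.46 ± 0.13 (SE, limma adjusted p = 2.18e-06). Insig2, a brake on sterol regulation, fell by 1.78 ± 0.16 (SE, limma adjusted p = 1.48e-06) at its brightest probe and stood at -2.93 at the lowest of the others. In each of these genes 5 of 5 restricted arrays lay apart from all standard diet arrays.

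In all, 2522 of 11148 probes passed, 1305 higher and 1217 lower, from 2187 genes. Of these, 290 changed more than 2-fold, 147 upward and 143 downward, and 4024 probes had an unadjusted p under 0.05. Other strong rises were those of the troponin Tnnc1 (3.03 ± 0.63), the neuronal regeneration protein Nrep (2.70 ± 0.31), Fos (2.53 ± 0.68) and the cytokine signalling inhibitor Cish (2.37 ± 0.73). Fos was 6.82, 8.66 and 10.24 in standard diet mice 1, 2 and 3. In standard diet mice 4 and 5 it was 11.85 and 11.38, within the restricted range (11.27 to 13.07). The Cish call ended in 4 of the 15 fits with 1 array left out (highest limma adjusted p 0.0759). The other strongest falls were those of Lcn2 (-4.10 ± 0.68), the adipocyte protease Cfd (-3.98 ± 0.63), Saa1 (-2.91) and Saa2 (-2.79), and the glutathione-degrading stress gene Chac1 (-2.65 ± 0.46).

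Heat shock transcripts rose, with a mean of 0.604 over 20 genes, led by Hsp90aa1 (1.51), Hspe1 (0.86) and Ahsa1 (0.52). Of them 10 rose and 0 fell over all probes, and 11 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.287 with an estimated correlation). The female-biased list rose by a mean of 1.14 over 8 genes. Its counts were 4 up and 0 down over all probes and 5 up and 0 down adjusted over the list alone (camera adjusted p = 0.00194, adjusted p = 0.287 with an estimated correlation). Beside Acot3 its rises included the thioesterase Acot4 (1.58) and the sulfotransferase Sult1a1 (0.44). The male-biased list shifted by -0.354 over 24 genes, 1 up and 2 down by both counts, over all probes and adjusted over the list alone (camera adjusted p = 0.0487, adjusted p = 0.783 with an estimated correlation). Ribosomal protein transcripts shifted by 0.2 over 38 genes, 13 up and 0 down by both counts, with Rps3 at 0.66 (camera adjusted p = 1.97e-05, adjusted p = 0.287 with an estimated correlation).

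The lists that fell included the proteasome, by a mean of 0.162 over 26 genes with Psmd4 at -0.49, 0 up and 7 down by both counts (camera adjusted p = 0.00194, adjusted p = 0.287 with an estimated correlation). The interferon list fell by a mean of 0.344 over 27 genes, with Usp18 at -1.29 and Rsad2 at -1.22. Here 1 rose and 6 fell over all probes, and 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.00775, adjusted p = 0.783 with an estimated correlation). The acute phase list had a mean of -0.888 and a median of -0.342 over 22 genes. Its calls were 0 up and 6 down over all probes and 0 up and 7 down adjusted over the list alone (camera adjusted p = 0.00376, adjusted p = 0.671 with an estimated correlation), lost in 3 of 11 other settings (highest adjusted p 0.567). The ubiquitin ligase, autophagy and FOXO list fell by a mean of 0.385 over 17 genes, with Gabarapl1 at -0.82, Ulk1 at -0.77 and Eif4ebp1 at -0.57. Among its genes were 1 up and 8 down by both counts (camera adjusted p = 0.00889, adjusted p = 0.179 with an estimated correlation). Adipocyte markers fell by a mean of 1.32 over 7 genes, with Plin4 (-1.71) and Pparg (-0.95) beside Cfd. That list held 1 up and 4 down over all probes and 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.0402, adjusted p = 0.287 with an estimated correlation). By fry, the interferon (adjusted p = 0.125), acute phase (adjusted p = 0.0686) and male-biased lists (adjusted p = 0.176) were not called, and the other 6 lists past camera were. The mean of the adipocyte markers was lower on every restricted liver array than on any standard diet array.

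Lists that did not pass camera still held single changes. For lipid synthesis, Elovl6, which elongates palmitate (1.73, adjusted p = 0.00106), and its regulator Srebf1 (1.19, adjusted p = 0.00235) rose among 7 up and 3 down of 19 genes. The sterol enzymes Fdps (-0.65), Hsd17b7 (-0.71) and Msmo1 (-1.09) fell, without a rise among the other 18 genes of their list. Their calls ended in 2, 4 and 5 of the 15 fits with 1 array left out (highest limma adjusted p 0.0695, 0.0747 and 0.0819). Other settings ended them in 4, 2 and 3 of 11. For sugar handling, Ppp1r3b (1.38) and the liver glycogen synthase Gys2 (0.90) rose, while Ppargc1a, the gluconeogenic coactivator, fell by 1.88 (adjusted p = 0.00395). Por, the electron donor of the P450s, rose by 1.68 ± 0.20 (adjusted p = 2.4e-05) and its regulator Nr1i3 by 0.97. Of the bile acid genes, the rate-limiting Cyp7a1 rose by 1.86 ± 0.42 (adjusted p = 0.00478), and Hsd3b7 (-1.10) and the export pump Abcb11 (-0.79) fell. Of 66 oxidative phosphorylation genes 12 rose and 2 fell, with Ndufb10 at 0.57 (camera adjusted p = 0.0798). The clock list went both ways, 5 up and 4 down of 15, with Per2 up by 2.20 ± 0.29 (adjusted p = 6.95e-05). Nr1d1, a clock repressor, was detected on 0 of 5 restricted arrays and 5 of 5 standard diet arrays, at least 3.25-fold lower (adjusted p = 8.05e-05). Fasn (0.88, adjusted p = 0.0397) and Igf1 (0.31, adjusted p = 0.0159) rose, whereas Pck1 (-0.83, adjusted p = 0.127), G6pc (-0.36, adjusted p = 0.332), Igfbp1 (-0.33, adjusted p = 0.85) and Fgf21 (0.17, adjusted p = 0.816) did not pass. The Fasn call ended in 6 of the 15 fits with 1 array left out (highest limma adjusted p 0.103) and in 5 of 11 other settings. With the summed signal as a covariate the count was 717, and Cyp7a1 (0.20, adjusted p = 0.886), Fos (1.95, adjusted p = 0.39), Tnnc1 (2.57, adjusted p = 0.215) and Por (0.71, adjusted p = 0.0992) were no longer past the test. Pparg (0.01), Ndufb10 (0.21) and Igf1 (0.14) were not called either. Nor were the proteasome list (camera adjusted p = 0.13) and the adipocyte list (camera adjusted p = 0.479), and the male-biased list lost its call in 8 of the 15 fits with 1 array left out. Of the 78 named genes past the test, 71 stayed past it with each array left out in turn and 38 in every other setting tried.

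Calorie restriction against metformin in liver asks where the interventions part, with the standard diet arrays only in the normalization and the pooled spread. Usp2, a clock-controlled deubiquitinase (probe ILMN_1240264, chromosome 9), stood 3.90 ± 0.52 higher under restriction on the log2 scale (SE, limma adjusted p = 9.5e-05), Acot3 3.33 ± 0.39 higher, Dbp 2.69 ± 0.39 higher and Cyp2a5 2.14 ± 0.13 higher (limma adjusted p = 2.61e-08). Lower under restriction were Cfd (-3.23 ± 0.63), Elovl3 (-3.08 ± 0.20), the matrix protein Spon2 (-2.80 ± 0.18) and Chrna4 (-2.72 ± 0.62). In all 1463 probes passed, 752 higher and 711 lower, from 1236 genes, and 237 changed more than 2-fold. The count was 1697 with the compared groups alone, 1453 with the summed signal as a covariate, and ran from 1040 to 1580 with each array left out.

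Cholesterol synthesis transcripts were lower under restriction than under metformin, with a mean log2 difference of -0.916 over 21 genes. None was higher, while 13 were lower over all probes and 16 adjusted over the list alone (camera adjusted p = 2.03e-08, adjusted p = 0.41 with an estimated correlation). Clock transcripts were 1.18 higher over 15 genes. The calls were 9 up and 2 down over all probes and 11 up and 3 down adjusted over the list alone (camera adjusted p = 5.41e-05, adjusted p = 0.0959 with an estimated correlation). The xenobiotic P450 list was 0.455 higher over 18 genes. Its calls were 5 up and 1 down over all probes and 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00147, adjusted p = 0.0959 with an estimated correlation). Female-biased genes were 0.844 higher, 4 up and 0 down of 8 by both counts (camera adjusted p = 0.00202, adjusted p = 0.41 with an estimated correlation). Heat shock genes were 0.438 higher, 9 up and 0 down of 20 over all probes and 11 up and 1 down adjusted over the list alone (camera adjusted p = 0.000158, adjusted p = 0.41 with an estimated correlation). Fatty acid oxidation genes were 0.157 higher, 6 up and 1 down of 24 over all probes and 7 up and 2 down adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.456 with an estimated correlation). The proteasome was lower (-0.218), 0 up and 9 down of 26 over all probes and 0 up and 12 down adjusted over the list alone (camera adjusted p = 2.84e-06, adjusted p = 0.0959 with an estimated correlation). Lymphocyte markers were lower (-0.732), 0 up and 2 down of 9 over all probes and 0 up and 7 down adjusted over the list alone (camera adjusted p = 0.00169, adjusted p = 0.467 with an estimated correlation). Collagens were lower (-0.222), 0 up and 4 down of 17 by both counts (camera adjusted p = 0.0169, adjusted p = 0.467 with an estimated correlation). Finally, macrophage markers were lower as a group (-0.402) with 0 of 18 past the test by either count (camera adjusted p = 0.014, adjusted p = 0.752 with an estimated correlation). Among the metformin mice, mice 22 and 23 had the highest liver means of the macrophage markers (9.45 and 9.16, other metformin mice 7.88 to 8.56) and of the lymphocyte markers (9.65 and 9.14, others 8.09 to 8.56). Without either of these mice the macrophage call ended (highest adjusted p 0.166), while the lymphocyte call held with each array left out. fry called neither list (adjusted p = 0.273 and 0.0744), and called the other 8. The collagen call ended in 2 such fits (highest adjusted p 0.066) and that of fatty acid oxidation in 1 (adjusted p = 0.0675).

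The next question was how far metformin changed the liver as restriction did. Both moved 160 probes up and 188 down, while 7 called probes went up under metformin and down under restriction, and 14 the other way. These counts have no reference value here, since the shared standard diet arrays favour shared directions. Across 8378 genes, which are not independent replicates, the fold changes of both diets correlated with r = 0.521 (jackknife SE 0.0958). Because both contrasts share the 5 standard diet arrays, unchanged simulated groups gave a mean r of 0.478, from -0.171 to 0.755 over 100 simulations. Their covariance averaged 0.0181 with a highest value of 0.0415, below the observed 0.0725. With separate standard diet arrays for each contrast, 2 and 3, the mean r over 20 splits was 0.328, from 0.0842 to 0.491. The standard diet liver arrays were all brighter by mean signal than the others. The simulations hold no offset common to a group, and split standard diet arrays would share one. Neither value therefore separates such an offset from a change shared by both diets. In muscle r was 0.386 over 8420 genes (jackknife SE 0.262) and the covariance of 0.0492 lay below the simulated mean of 0.0672. The muscle simulations include the array of mouse 27 and spread widely, with r from -0.625 to 0.938. They do not decide whether the diets moved muscle alike. Without the muscle array of mouse 27 the observed r was 0.6 and the covariance 0.051, with no simulation run to set beside them.

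**Figure D3:**
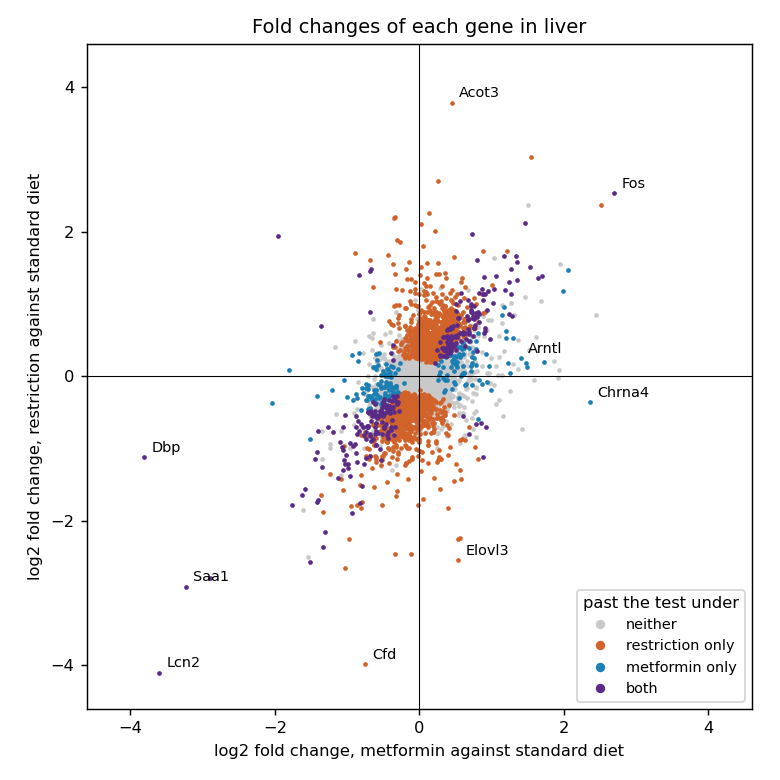
Log2 fold change of each gene in liver under metformin (horizontal axis) and under calorie restriction (vertical axis), both against the standard diet, 1 point per gene, coloured by the comparisons in which it passed the test. Lcn2 lies at -3.60 and -4.10, Dbp is lowest under metformin at -3.81, and Acot3 stands at 3.78 under restriction alone.

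Metformin against the standard diet in muscle asks whether the drug acts there too. limma called 0 of 10983 probes, with a smallest adjusted p of 0.117, while 547 probes had an unadjusted p under 0.05. The smallest p belonged to Nfatc3, a calcium-dependent transcription factor, at -1.04 ± 0.17 (SE, limma adjusted p = 0.117), Nhlrc2 at -0.83 ± 0.15, and the lipid droplet protein Plin5 at -1.20 ± 0.24. Hey1, a Notch target, stood at 1.02 ± 0.21, the cGMP kinase Prkg1 at -1.03 ± 0.22, and the mitochondrial coactivator Ppargc1a at -0.81 ± 0.27. Pdk4 (-0.80), the uncoupling protein Ucp3 (-0.61), the atrophy ligase Fbxo32 (0.26) and the glucose transporter Slc2a4 (-0.06) did not pass. Srxn1 (-1.23) with adjusted p = 0.975 did not either, and Hk2 is not analysed here because it did not meet the detection filter.

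As groups, hepatocyte markers stood 1.84 higher over 8 genes, with 0 past the test over all probes and 8 up and 0 down adjusted over the list alone (camera adjusted p = 4.66e-10, adjusted p = 0.156 with an estimated correlation). Apoa1, a lipoprotein made by liver, was detected on 3 of 5 metformin arrays and 0 of 5 standard diet arrays, at least 3.46-fold higher. The marker mean was 8.97, 7.65 and 7.48 on the arrays of metformin mice 21, 22 and 23, and 4.71 to 5.26 on the standard diet arrays. Collagen and matrix transcripts were lower by a mean log2 fold change of -0.405 over 22 genes, led by Timp1 (-1.09), Mmp2 (-0.44) and Bgn (-0.40). The list had 0 genes past the test by either count (camera adjusted p = 2.62e-07, adjusted p = 0.121 with an estimated correlation). Adipocyte markers stood 0.989 higher over 9 genes. They had 1 up and 0 down adjusted over the list alone and 0 over all probes (camera adjusted p = 0.000296, adjusted p = 0.306 with an estimated correlation). The fatty acid oxidation list stood at -0.198 over 23 genes, with 0 up and 2 down adjusted over the list alone and 0 over all probes (camera adjusted p = 0.00449, adjusted p = 0.306 with an estimated correlation).

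The other 8 lists past camera in this comparison held 0 genes past the test by either count. Those above 0 were lymphocyte markers (0.452, adjusted p = 0.00448, adjusted p = 0.26 with an estimated correlation), the proteasome (0.142, adjusted p = 0.00448, adjusted p = 0.116 with an estimated correlation) and cholesterol synthesis (0.221, adjusted p = 0.00721, adjusted p = 0.19 with an estimated correlation). So were gluconeogenesis and amino acid breakdown (0.242, adjusted p = 0.00779, adjusted p = 0.116 with an estimated correlation) and fast fibre genes (0.16, adjusted p = 0.0167, adjusted p = 0.306 with an estimated correlation). Those below 0 were oxidative phosphorylation (-0.0682, adjusted p = 0.00721, adjusted p = 0.306 with an estimated correlation), slow fibre genes (-0.255, adjusted p = 0.012, adjusted p = 0.552 with an estimated correlation) and macrophage markers (-0.19, adjusted p = 0.038, adjusted p = 0.419 with an estimated correlation). With single arrays left out, the calls of macrophage markers ended in 5 fits (highest adjusted p 0.165), slow fibre genes in 3 (0.441) and oxidative phosphorylation in 2 (0.0775). Fast fibre genes (0.181), lymphocyte markers (0.0838) and cholesterol synthesis (0.0691) lost theirs in 1 fit each. Over 11 other settings, macrophage markers lost the call in 4 (highest adjusted p 0.279), fast fibre genes in 3 (0.72), and slow fibre genes (0.257) and cholesterol synthesis (0.214) in 2 each. Oxidative phosphorylation (0.456), the proteasome (0.068) and fatty acid oxidation (0.0637) lost it in 1 each. fry called 0 lists in every muscle comparison. The count of called probes was 4 without standard diet mouse 1, 45 without restricted mouse 27, 46 when muscle was also normalized anew without mouse 27, 84 with the compared groups alone and 673 with array weights. With mouse 27 left out in this way, Nfatc3 (-1.05, adjusted p = 0.00667), Nhlrc2 (-0.82, adjusted p = 0.00667), Plin5 (-1.19, adjusted p = 0.0153), Ppargc1a (-0.80, adjusted p = 0.0306) and Timp1 (-1.12, adjusted p = 0.0322) passed.

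**Figure D4:**
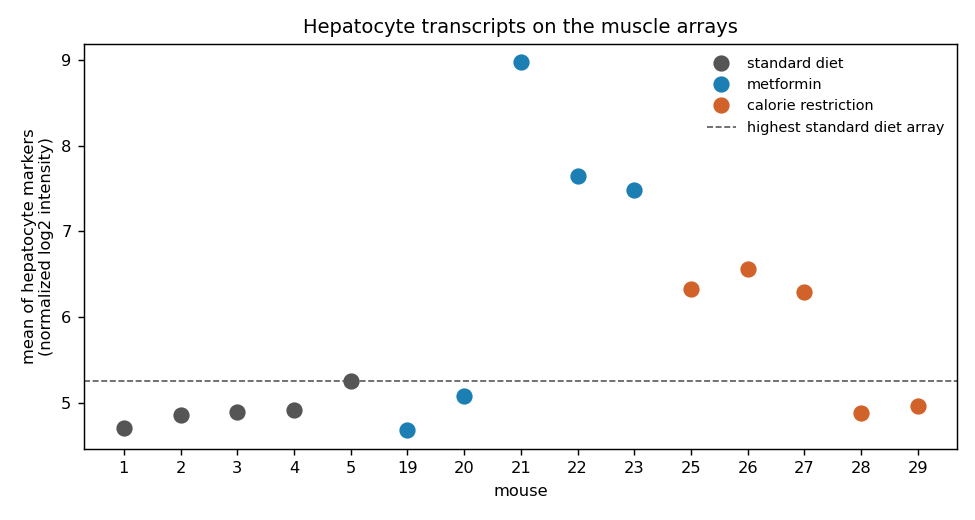
Mean normalized log2 intensity of the hepatocyte markers (vertical axis) on the muscle array of each mouse (horizontal axis), coloured by diet, with a dashed line at the highest standard diet array. Metformin mice 21, 22 and 23 and restricted mice 25, 26 and 27 lie above the line at 5.26, and the other 4 treated mice below it.

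Calorie restriction against the standard diet in muscle gave fewer called probes than in liver, 79 against 2522. The fits differ in power: on simulated data the muscle fit found 49 of 100 genes changed by a log2 of 1, and the liver fit 88. Whether fewer transcripts changed in muscle was not tested. G0s2, an inhibitor of fat breakdown (probe ILMN_1257299, chromosome 1), rose from 8.22 ± 0.65 (SD, n = 5) to 10.39 ± 0.70 (SD, n = 5), a log2 fold change of 2.17 ± 0.35 (SE, limma adjusted p = 0.01). Per2, a clock repressor (probe ILMN_2987862, chromosome 1), rose by 1.48 ± 0.23 (adjusted p = 0.00763). Nr1d1 fell to 6.21 ± 0.58 (SD, n = 5) from 8.16 ± 0.41 (SD, n = 5), a log2 fold change of -1.95 ± 0.29 (SE, limma adjusted p = 0.00664). Per2 and Nr1d1 thus moved in their liver directions. The stress-induced Ier3 (1.61 ± 0.25), Egr1 (1.37 ± 0.29), Hey1 (1.24 ± 0.21) and the methyltransferase Inmt (1.12 ± 0.22) also rose. The calls of Egr1 and Inmt ended in 10 and 5 of the 15 fits with 1 array left out (highest limma adjusted p 0.135 and 0.111). Bach1, a repressor of antioxidant genes (-1.97 ± 0.30), the unconventional myosin Myo10 (-1.74 ± 0.31), the microtubule protein Map1b (-1.73 ± 0.30) and the pericyte gene Rgs5 (-1.69 ± 0.30) fell. The metformin muscle arrays also lay apart from the standard diet in Bach1 (5.91 to 6.58 against 7.03 to 8.33), Rgs5 (7.58 to 8.33 against 8.55 to 9.21) and Hey1 (8.58 to 9.28 against 7.55 to 8.45). In Per2, Nr1d1 and Myo10 they overlapped it. Standard diet muscle arrays stood apart in median and lowest signal, and whether that stands behind moves shared by both diets was not tested.

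In all 79 of 10983 probes passed, 12 higher and 67 lower, from 73 genes, 52 of them changed more than 2-fold and 1332 had an unadjusted p under 0.05. Fbxo32 (-1.27, adjusted p = 0.127) and Nfic (-1.47, adjusted p = 0.476) did not pass at their brightest probe, though dimmer probes of both did, at up to -2.50 and -2.09. Trim63, the other atrophy ligase (-1.57, adjusted p = 0.227), the cell cycle inhibitor Cdkn1a (-1.56, adjusted p = 0.201), Ppargc1a (-0.91, adjusted p = 0.173), Pdk4 (-0.61, adjusted p = 0.428), Ucp3 (-0.60, adjusted p = 0.58) and Slc2a4 (-1.01, adjusted p = 0.516) did not pass. The array of mouse 27 carries much of several of these values. With muscle normalized anew without it, Trim63 (-0.89, adjusted p = 0.00895) and Fbxo32 (-0.91, adjusted p = 0.0435) passed. Cdkn1a (-1.09), Ppargc1a (-0.62), Pdk4 (-0.38), Nfic (-0.29), Slc2a4 (-0.03) and Ucp3 (0.06) did not.

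The list of these ligases, autophagy genes and FOXO targets stood at -0.619 over 17 genes. It had 0 past the test over all probes and 0 up and 3 down adjusted over the list alone (camera adjusted p = 0.0278, adjusted p = 0.784 with an estimated correlation). Collagens stood at -0.366 over 22 genes, 0 over all probes and 0 up and 4 down adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.784 with an estimated correlation). The insulin signalling list stood at -0.314 over 25 genes with 0 past the test by either count (camera adjusted p = 0.0349, adjusted p = 0.784 with an estimated correlation). Adipocyte markers stood at 0.925 over 9 genes with 0 past the test by either count (camera adjusted p = 0.0278, adjusted p = 0.784 with an estimated correlation). The array of mouse 26 had an adipocyte mean of 11.33, where standard diet arrays had 7.57 to 8.08. Hepatocyte markers stood at 0.875 (camera adjusted p = 0.112). Each of these 4 list calls ended in some fits with 1 array left out. Adipocyte markers lost theirs without restricted mouse 26 (adjusted p = 0.577) and in 1 more fit, insulin signalling in 4 fits (highest adjusted p 0.0706), the ligase list in 2 (0.0628) and collagens in 1 (0.0706). Over 11 other settings insulin signalling lost its call in 5 (highest adjusted p 0.14), the ligase list in 3 (0.106) and adipocyte markers in 2 (0.12). Normalized anew without mouse 27, the ligase and insulin lists both had adjusted p = 0.0516. The probe count was 26, 45 and 41 without standard diet mice 2, 3 and 4, and 229 without restricted mouse 27, the array that detected the fewest probes. It was 17 with the compared groups alone, 40 with no filter on dim probes, 120 with the deposited z-scores and 369 with array weights. Of the 13 named genes past the test, 6 stayed past it with each array left out in turn and 3 in every other setting tried. Median scaling in place of quantile normalization moved the median log2 fold change of all probes to -0.26, and Hey1 (0.90) and Inmt (0.82) were then no longer past the test, Hey1 with adjusted p = 0.103.

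Calorie restriction against metformin in muscle gave 3 probes, 2 higher and 1 lower. Of these, 2 were probes of Per2, 2.07 ± 0.23 higher under restriction at the brighter one (SE, limma adjusted p = 0.000833), which stayed past the test in every setting tried. The third was an unnamed gene model, LOC100047427, named here after its values were seen, at -1.99 (limma adjusted p = 0.000269). Slow fibre genes stood 0.463 higher (camera adjusted p = 0.038), glycolysis genes at -0.312 (camera adjusted p = 0.0449), the ligase, autophagy and FOXO list at -0.568 (camera adjusted p = 0.0449) and hepatocyte markers at -0.965 (camera adjusted p = 0.0449), each with adjusted p = 0.656 with an estimated correlation. None of the 4 lists held a gene past the test over all probes, and the FOXO list held 0 up and 2 down adjusted over the list alone, the others 0. With 1 array left out, the FOXO list (highest adjusted p 0.0873) and hepatocyte markers (0.374) lost their calls in 5 fits each, glycolysis in 4 (0.211) and slow fibre genes in 3 (0.349). Other settings ended the glycolysis call in 7 of 11 (highest adjusted p 0.93), the FOXO call in 5 of 11 (0.231), the slow fibre call in 3 of 11 (0.158) and the hepatocyte call in 3 of 9 (0.183). Anew without mouse 27 glycolysis had adjusted p = 0.211. The probe count was 37 without restricted mouse 27 and 5 without standard diet mouse 1, and 1110 probes had an unadjusted p under 0.05.

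**Figure D5:**
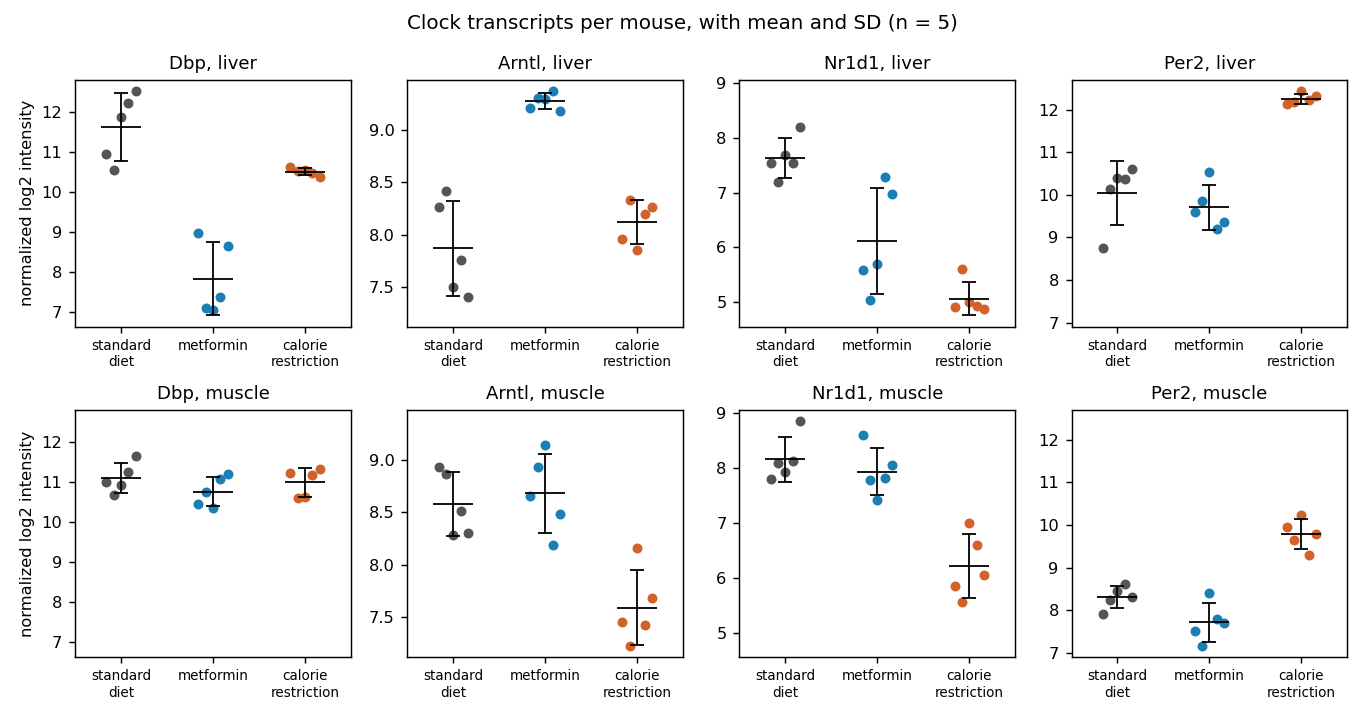
Normalized log2 intensity of Dbp, Arntl, Nr1d1 and Per2 (vertical axes) in liver (upper panels) and muscle (lower panels) for each diet, 1 point per mouse, with the mean and SD of 5 mice. Liver Dbp is 7.82 under metformin and 11.63 on the standard diet, and muscle Per2 is 9.79 under restriction and 8.31 on the standard diet.

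The last comparison tested whether each diet acted differently on liver and muscle of the same mice, as the liver change minus the muscle change. For metformin, Dbp differed by -3.47 ± 0.48 (SE, limma adjusted p = 0.000697), with -3.81 in liver and -0.33 in muscle, and the splicing factor Srsf7 by 1.21 ± 0.22 (limma adjusted p = 0.0262). These were the 2 probes past the test of 9164, with 742 at an unadjusted p under 0.05. Dbp kept its call with each array left out and Srsf7 did not (highest adjusted p = 0.0925), and 75 probes passed without the muscle array of restricted mouse 27. For restriction, Nrep (2.71 ± 0.40), the alkaline phosphatase Alpl (2.10 ± 0.35) and the haem synthesis enzyme Alas1 (2.03 ± 0.30) rose more in liver. Cfd (-5.36 ± 0.92), the helicase Blm (-2.47 ± 0.40), the serine dehydratase Sds (-2.30 ± 0.45) and Trib3 (-2.05 ± 0.37) fell in liver relative to muscle. In all 252 probes from 239 genes passed, 114 above 0 and 138 below, and 149 with each mouse as a fixed block.

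The clock list under metformin differed by -0.763 over 14 genes. It had 0 up and 1 down over all probes and 1 up and 4 down adjusted over the list alone, and passed with the preset correlation (camera adjusted p = 0.000803), by fry (adjusted p = 0.0122) and with an estimated one (adjusted p = 0.0405). So did gluconeogenesis and amino acid breakdown at -0.733 over 9 genes, 0 over all probes and 0 up and 4 down adjusted over the list alone (camera adjusted p = 2.17e-06, adjusted p = 0.00501 with an estimated correlation), in a group where 3 muscle arrays carried hepatocyte transcripts. The others above 0 were collagens (0.527, camera adjusted p = 5.54e-06, adjusted p = 0.132 with an estimated correlation), cholesterol synthesis (0.448, camera adjusted p = 0.00178, adjusted p = 0.384 with an estimated correlation) and ribosomal proteins (0.14, camera adjusted p = 0.00593, adjusted p = 0.314 with an estimated correlation). Above 0 too were macrophage markers (0.361, camera adjusted p = 0.0172, adjusted p = 0.437 with an estimated correlation), oxidative phosphorylation (0.139, camera adjusted p = 0.0217, adjusted p = 0.437 with an estimated correlation) and endothelial markers (0.321, camera adjusted p = 0.0224, adjusted p = 0.314 with an estimated correlation). The others below 0 were the acute phase (-0.929, camera adjusted p = 0.00116, adjusted p = 0.246 with an estimated correlation), adipocyte markers (-1.3, camera adjusted p = 0.00116, adjusted p = 0.307 with an estimated correlation) and interferon genes (-0.287, camera adjusted p = 0.00527, adjusted p = 0.437 with an estimated correlation). With 1 array left out, oxidative phosphorylation lost its call in 6 fits (highest adjusted p 0.12), macrophage markers in 4 (0.2), endothelial markers in 3 (0.0715) and interferon genes in 1 (0.0551). Each of these also lost it in 2 of 11 other settings, and cholesterol synthesis (0.0911) and the acute phase (0.0794) in 1. fry called none of the lists of this paragraph but clock and gluconeogenesis (adjusted p = 0.00108), the others having adjusted p of 0.117 and above.

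Under restriction the interferon list differed by -0.64 over 20 genes. In it were 0 up and 3 down over all probes and 0 up and 6 down adjusted over the list alone (camera adjusted p = 0.000183, adjusted p = 0.257 with an estimated correlation). Adipocyte markers differed by -2.3 over 7 genes, 0 up and 2 down over all probes and 0 up and 4 down adjusted over the list alone (camera adjusted p = 0.000326, adjusted p = 0.188 with an estimated correlation). Clock genes differed by 0.546 over 14 genes, 2 up and 0 down over all probes and 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis differed by -0.503 over 16 genes, 0 up and 2 down over all probes and 0 up and 4 down adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.428 with an estimated correlation). Heat shock genes (0.675, camera adjusted p = 0.0121, adjusted p = 0.248 with an estimated correlation) and ribosomal proteins (0.305, camera adjusted p = 0.0132, adjusted p = 0.258 with an estimated correlation) also lay above 0. Gluconeogenesis (-0.654, adjusted p = 0.188 with an estimated correlation), the acute phase (-0.979, adjusted p = 0.317 with an estimated correlation) and the proteasome (-0.137, adjusted p = 0.188 with an estimated correlation) lay below it, each with a camera adjusted p = 0.0218. With 1 array left out, the clock (highest adjusted p 0.0943), acute phase (0.143), cholesterol (0.0817) and proteasome (0.0787) calls ended in 3 fits each and gluconeogenesis in 2 (0.0577). Other settings ended the clock and acute phase calls in 4 of 11 each, gluconeogenesis in 3 of 9, cholesterol and ribosomal proteins in 2 of 11 each, and heat shock and the proteasome in 1 of 11 each. Anew without muscle mouse 27 the clock list had adjusted p = 0.0938. fry did not call cholesterol synthesis (adjusted p = 0.165), the acute phase (0.1), the proteasome (0.0774) or ribosomal proteins (0.0774). The restriction count was 391, 644 and 406 without the muscle arrays of restricted mice 25, 27 and 29.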

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

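The test of liver RNA in the muscle samples was written before its result was seen, and the tests of the metformin group's markers, of the clock genes and of array brightness were chosen after the results they concern were seen.

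Hepatocyte transcripts stood out on 6 muscle arrays, those of metformin mice 21, 22 and 23 and restricted mice 25, 26 and 27. If liver RNA was carried into these samples, other liver-abundant genes must rise with them in the order of their liver level, and across 100 such genes that no standard diet muscle array detects the rank correlation of rise and liver level was 0.35 at the lowest of the 6 and 0.77 at the highest. Of these 100 genes, 83, 32 and 30 were detected on the arrays of metformin mice 21, 22 and 23, and 12, 21 and 5 on those of restricted mice 25, 26 and 27. Median rises ran from 1.01 (mouse 21) to 0.15 (mouse 27). The other treated arrays, of mice 19, 20, 28 and 29, detected 1, 1, 3 and 2 of them. Standard diet arrays detected 0 by the choice of genes and are no reference here. The values that carried-over liver RNA needs are thus there, and it is a candidate explanation. A rise of the markers in every mouse of the metformin group is excluded, since 3 of its 5 arrays stood above the highest standard diet array and mice 19 and 20 did not. A change of these transcripts within the muscle of single mice was not tested, so the hepatocyte, gluconeogenesis and acute phase values of muscle, and the tissue differences that use them, cannot be read as muscle expression.

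Clock genes shifted under both diets, and the labels used here give no hour of sampling or feeding. Under metformin, an hour of sampling shared by both tissues would shift liver and muscle of a mouse alike. The clock list differed between them by -0.763 (camera adjusted p = 0.0405 with an estimated correlation), which argues against that hour as the whole cause. This holds unless both clocks answer to the hour unequally, which was not tested. Of the list's genes, only Dbp passed the test of the difference over all probes (-3.47). In muscle some clock genes, such as Ciart, also stood lower under metformin, and others, such as Bhlhe40, stood higher. A single standard diet mouse is excluded as the source of the shift. The mean shift of -0.879 stayed at -0.80 or further from 0 with each standard diet mouse left out in turn. Standard diet mouse 1 did lie apart for some clock genes in liver, such as Ciart (5.12, others 7.48 to 9.01) and Per1 (6.90, others 8.87 to 10.13). It also did for Per1 in muscle (7.42, others 9.02 to 10.47), but not for liver Dbp (10.94, others 10.55 to 12.53). Without mouse 1 the mean liver shift was -1.04. Under restriction, the hour of sampling or feeding shared by both tissues would move both alike, and 2 of 2 genes tested, Nr1d1 and Per2, passed the test in muscle in the liver's direction. These genes were chosen after their results were seen, and their moves may come from that hour or from the diet. The clock list as a whole differed between the tissues (camera adjusted p = 0.0218, adjusted p = 0.188 with an estimated correlation). Arntl stood at 0.25 in liver and -0.99 in muscle (difference 1.24, limma adjusted p = 0.0145). A shared hour is thus neither shown nor excluded under restriction. An effect of metformin on the liver clock stays open beside a liver-specific feeding rhythm, untested here.

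By mean signal, standard diet liver arrays were all brighter than those of both other diets, so the brighter standard diet liver arrays could stand behind calls shared by both comparisons. By median signal, the arrays of metformin mice 19 and 20 (164.5 and 167.1) lay within the standard diet range (163.1 to 178.3). Those of metformin mice 21, 22 and 23 did not (135.1 to 137.6). With the log2 summed signal as a covariate, the fold changes of the called probes kept their size on the whole. Slopes were 1.23 for metformin and 1.07 for restriction (lowest with an array left out, 1.12 and 1.03), where under 0.5 was predicted for that cause. Single genes moved both ways under metformin, Lcn2 from -3.60 to -6.92 and Idi1 from 1.47 to 0.56. The median absolute log2 fold change went from 0.61 to 0.66 and from 0.55 to 0.56, and the median SE from 0.15 to 0.30 and from 0.14 to 0.25. Some calls thus ended as the error grew and others as the fold change shrank. Of the 632 metformin calls 36 passed again, and of the 2522 restriction calls 541. Brightness as it acts within groups thus does not account for the fold changes as a whole. Which single genes it touches stays open (Cyp7a1 went from 1.86 to 0.20 under restriction). No array of another diet was as bright by its summed signal, so whether brightness acts alike between the groups cannot be decided by this fit. The bound was set at the lowest slope after the slopes were seen. Restriction against metformin, where brightness overlaps, gave 1463 and 1453 probes without and with the covariate.

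Single arrays far from the other 4 of their group were looked for in 606 groups by Dixon's test at 95%, and 41 stood out, 11 of them on the muscle array of mouse 27, where about 1 in 20 groups would by chance. The mean signal over all probes was 770.4 on the muscle array of standard diet mouse 1, and that of restricted mouse 27 detected 6848 probes.

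In liver, these were on the standard diet the log2 intensities of Socs2 (10.13), Chac1 (8.34) and Per2 (8.74) in mouse 1, Hspe1 (10.47) in mouse 2, Atf4 (11.28) and Slco1a4 (8.32) in mouse 3, and Acat2 (10.17), Saa4 (13.47), Mcm5 (7.48) and Tnnc1 (6.54) in mouse 4. Under metformin they were Atp5e (8.53) and Pparg (9.20) in mouse 19, and Gpt2 (11.93), Rps4x (13.68) and Cdh5 (6.92) in mouse 22. Under restriction they were Eng (9.22), Nr1d1 (5.60) and Sox9 (5.99) in mouse 26, Spon2 (8.39) in mouse 27, Ppp1r3b (11.74) and Emcn (8.17) in mouse 28, and Birc5 (5.45) and Igf1 (13.03) in mouse 29.

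In muscle, these were Pmvk (6.06) in standard diet mouse 1, Atp5j (14.41) and Thrsp (5.92) in standard diet mouse 3, Psmd8 (11.60) in metformin mouse 21, Acat2 (6.84) in metformin mouse 23 and Col4a1 (10.98) in restricted mouse 26. On the array of restricted mouse 27 they were Psmd13 (11.19), Srxn1 (5.80), Ucp3 (4.63), Slc2a4 (6.12), Nfic (4.89), Bach1 (4.54), Cdkn1a (5.79), Trim63 (5.31), Rgs5 (5.79) and Pdgfrb (5.11).

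The effect of a diet differed between liver and muscle, by the test of the difference itself, for 27 of the named gene and diet pairs, given as the liver minus the muscle log2 fold change. Under metformin these were Dbp (-3.47) and Srsf7 (1.21). Under restriction, the difference was above 0 for Nrep (2.71), Alpl (2.10), Alas1 (2.03), Acot1 (1.93), Myo10 (1.56), Arntl (1.24), Por (1.24), Nhlrc2 (0.97), Nfatc3 (0.94) and Srsf7 (0.88). It was below 0 for Cfd (-5.36), Blm (-2.47), Sds (-2.30), Trib3 (-2.05), Plin4 (-1.94), Usp18 (-1.70), Spon2 (-1.63), Hsd3b7 (-1.61), Gstm4 (-1.49), Insig2 (-1.33), Acat2 (-1.21), Ngfr (-1.20), Mcm5 (-1.19), Fdps (-0.92) and Psmd4 (-0.59). Arntl rose by less than its error allows to call in liver (0.25) and stood at -0.99 in muscle. Cfd fell in liver (-3.98) and stood at 1.38 in muscle, where the adipocyte marker means of the arrays varied.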

How the results depend on the processing

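The summed-signal covariate and muscle normalized anew without the array of mouse 27 were chosen after seeing the data. Unless a cause is given, the cause was not tested. Direction held for each named gene past the test in each setting, except those listed at the end, and Lcn2 and Upp2 of the 47 named genes called for metformin in liver, 38 of 78 for restriction in liver, and 3 of 13 in muscle stayed past the test in every setting but the left-out arrays.

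Called probes, metformin against the standard diet in liver, 632: 355 with no filter on dim probes, where 25594 are tested, 421 with array weights, 110 with the groups compared only, where fewer arrays set the error, and 104 with the summed signal as a covariate, where the error grew. Leaving out 1 array gave 183 (standard diet mouse 3) to 1163 (mouse 1), with 351 and 315 without standard diet mice 2 and 4 and 377, 264 and 309 without metformin mice 21, 22 and 23. Restriction in liver, 2522, fell to 717 with the covariate and stayed within 1846 to 2581 with 1 array left out. Restriction against metformin in liver, 1463, stayed within 1.5 times in each setting, 1040 to 1580 with 1 array left out.

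Metformin in muscle, 0: 1 each with rebuilt z-scores, no background correction and median scaling, 673 with array weights, which gave mouse 27 a weight of 0.0302, 84 with the groups compared only, 46 with muscle normalized anew without mouse 27, and 0 to 45 with 1 array left out (4 without standard diet mouse 1, 45 without mouse 27). Restriction in muscle, 79: 120 with the deposited z-scores, 40 with no filter, 369 with weights, 17 with the groups compared only, 229 anew without mouse 27, and 26 to 229 with 1 array left out (26, 45 and 41 without standard diet mice 2, 3 and 4, 229 without mouse 27). Restriction against metformin in muscle, 3: 14 and 5 with rebuilt and deposited z-scores, 7 with detection on all 15 arrays, 74 with weights, 37 anew without mouse 27, and 3 to 37 with 1 array left out (5 without standard diet mouse 1, 37 without mouse 27). The array of mouse 27, with the fewest probes detected, thus lowers each muscle count.

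Tissue difference of metformin, 2: 6 with rebuilt z-scores, 4 with no background correction, 1 with median scaling, 10 with no filter, 331 with weights, 81 anew without mouse 27. With 1 array left out it ran from 1 to 75: 75 without muscle mouse 27, 4 without liver standard diet mouse 2 or muscle metformin mouse 20, and 1 without liver mice 1, 3, 4, 19, 20 or 21 or muscle mice 1, 22 or 23. Tissue difference of restriction, 252: 442 with no background correction, 158 with median scaling, 395 with no filter, 780 with weights, 149 with the mouse as a fixed block, 646 anew without mouse 27, and 177 to 644 with 1 array left out (391, 644 and 406 without muscle mice 25, 27 and 29).

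The correlation of metformin and calorie restriction fold changes, liver, 0.521, was 0.796 with the covariate, 0.328 with the standard diet arrays split, which removes the shared arrays, and 0.487 to 0.58 with 1 array left out. That of muscle, 0.386, ran from 0.297 to 0.601 with 1 array left out.

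Lists called in liver for metformin, 5: 0 with an estimated correlation, 8 with rebuilt and 8 with deposited z-scores, 13 with no filter, 12 with the covariate, 3 with fry, and 3 (without standard diet mouse 2) to 10 (without metformin mouse 19) with 1 array left out, with 8 without standard diet mouse 5 and 9 and 8 without metformin mice 21 and 23. For restriction, 9: 0 with an estimated correlation, 14 with the groups compared only, 15 with the covariate, and 7 to 14 with 1 array left out (14 without standard diet mouse 3). For restriction against metformin, 10: 0 with an estimated correlation, and 8 to 11 with 1 array left out.

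Lists called in muscle for metformin, 12: 0 with an estimated correlation, 6 with rebuilt z-scores, 6 with detection on all 15 arrays, 0 with fry, and 10 to 13 with 1 array left out. For restriction, 4: 0 with an estimated correlation, 2 with weights, 2 with rebuilt and 8 with deposited z-scores, 10 with median scaling, 1 with detection on all 15 arrays, 0 with fry, and 2 to 5 with 1 array left out (2 without standard diet mouse 2 or restricted mouse 29). For restriction against metformin, 4: 0 each with an estimated correlation, the mean of all probes, no intensity trend and fry, 7 with weights, 2 with rebuilt z-scores, 2 with median scaling, 7 with no filter, 11 anew without mouse 27, and 1 (without metformin mice 20, 22 or 23 or restricted mouse 29) to 11 (without mouse 27) with 1 array left out. Tissue difference of metformin, 11: 2 with an estimated correlation, 7 with rebuilt z-scores, 5 with detection on all 15 arrays, 2 with fry, and 9 to 12 with 1 array left out. Tissue difference of restriction, 9: 0 with an estimated correlation, 4 with rebuilt z-scores, and 6 to 10 with 1 array left out.

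Some values changed direction. With rebuilt z-scores these were Birc5 (0.02), which had passed, and Igfbp1 (-0.30) in liver under metformin, Pmvk (-0.03) in muscle under metformin, Ucp3 (0.01) in muscle under restriction, and the list glycolysis and glycogen, calorie restriction against metformin, muscle (adjusted p = 0.93, and 0.733 with deposited z-scores). With the covariate in liver they were Pparg under metformin (0.52) and under restriction (0.01), where it had passed, G6pc (-0.07) and Igfbp1 (-4.77) under metformin. With 1 array left out, they were Cyp7a1 under metformin (-0.60 to 0.09, the latter without standard diet mouse 4), Igfbp1 under restriction (-1.08 without standard diet mouse 1, but 0.30, 0.04 and 0.09 without standard diet mice 2, 3 and 4, 0.18 without restricted mouse 27), Fgf21 under restriction (-0.16 without standard diet mouse 4, to 0.51) and Ucp3 in muscle under restriction (-0.80 without mouse 29, 0.06 without mouse 27, and 0.06 anew without it). With median scaling, Fdps in muscle under restriction was -0.07, where the median of all probes was -0.26.

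A block for the array slide could not be run, since the files give no slide; camera has no robust variance, and the mouse as a random block was not run for lists. Signal over background limits which dim probes can be tested, and an array detected 10288 to 11172 probes in liver and 6848 to 11378 in muscle.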

Other observations

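The counts of splits were planned and their predictions written before the counts were seen. For each comparison, 100 of the 126 splits of its 10 arrays, or of its 10 mice, into other groups of 5 were refitted, the real split among them. Chance can be excluded for restriction in liver (1 split with as many probes, the real 2522, highest other 84), for restriction against metformin in liver (1, real 1463, highest other 1), for restriction in muscle (1, real 79, highest other 2) and for the tissue difference of restriction (1, real 252, highest other 0). It can be excluded for metformin in liver (1, real 632, highest other 293), although 19 other splits called at least 1 probe. Splits that exchange few arrays keep part of the diet difference, so these calls do not by themselves show further structure among these arrays. Small counts were those of restriction against metformin in muscle (2 splits, real 3, highest other 5) and of the tissue difference of metformin (2, real 2, highest other 4). Their share of splits met the planned limit for excluding chance, but in each 1 other split called more than the real one. Chance therefore stays possible for both. For metformin in muscle the real count is 0, which all 100 splits reach whatever the data (highest other 0), so the splits say nothing about chance there.

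The mean of the adipocyte markers stood above all standard diet muscle arrays (7.57 to 8.08) in metformin mice 23, 22, 19 and 21 (9.58, 9.34, 8.88 and 8.48) and in restricted mice 26, 27, 25 and 28 (11.33, 8.49, 8.32 and 8.15), and not in metformin mouse 20 (7.93) or restricted mouse 29 (7.61). Lymphocyte markers in liver were highest in metformin mice 22 (9.65) and 23 (9.14) and standard diet mouse 1 (9.19). Both are given as values, and no explanation was tested.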
